A study of Arabidopsis thaliana with 6 samples.

How the data were processed

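Total RNA was extracted from callus with TransZol Up and libraries were made from 1 µg with a TruSeq RNA kit, per the labels' protocols. There were 6 libraries, 3 from day 7 and 3 from day 12, which the series describes as biological replicates; whether they came from separate plants or plates was not given in the sources used here. Deposited counts (whole numbers, not normalized) and deposited TPM values, which sum to the same total in each library, covered the same 36793 loci in a different row order. Per the submitters' processing notes, STAR 2.7.10a, RSEM 1.3.1 and the TAIR10 build were used; which tool made which table, the strand setting and the treatment of reads that map to several places were not given in the sources used here. Reads from antisense or overlapping genes and from near-identical copies therefore cannot be told apart. Columns were matched to samples by name, with 0 columns unmatched. Each replicate pair within a day differed by more than counting noise, so all 6 libraries were used.

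Gene names were taken from the RefSeq table of assembly TAIR10.1 for names only; 36629 loci matched, and the 164 plastid and mitochondrial loci did not. No coordinates are printed because that assembly is not the build named by the submitters. Of 596 members in 33 gene lists fixed before the data were examined, 579 carried the same name in the reference and were kept.

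The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 18364, scaled with TMM factors (0.960 to 1.04) and fitted with robust quasi-likelihood models with day as the only term. Log2 changes are day 12 minus day 7, a standard error is the change divided by the root of its F statistic, and p-values were adjusted by Benjamini-Hochberg at 0.05. CPM values are scaled by the TMM factors. They are given as mean ± SD of 3 libraries. A count of 3 stands for 0.279 to 0.609 CPM in a library. Counting intervals (95%, exact) and floors cover counting error only. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over 32 lists. The embryo and seed maturation list had 2 tested members and was not tested.

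The named genes follow a rule fixed before the data were examined. It takes the 6 largest fitted rises and 6 largest fitted falls among called genes with a reference symbol, at least 5 CPM in the higher day and all libraries of one day above those of the other. From each list it takes up to 3 called genes of lowest adjusted p and, if these go one way, the called gene of lowest adjusted p in the other direction; where none was called, the gene of lowest p is given as values. It also takes 9 regulators wherever they were tested.

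Libraries with the same replicate number deviated together from their day means (correlations of 0.15, 0.16 and 0.24 across genes, against -0.16 to 0.01 for other pairs). The numbers may therefore mark a pairing, which the labels do not name. A fit with the replicate number as a block was made beside the main fit, which leaves the number out. Within a day Spearman correlations were 0.966 to 0.983, and between days 0.926 to 0.962.

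The procedure was tested on simulated counts for this comparison, with 18210 genes tested. It recovered 13 of 65 genes changed 1.5-fold, 53 of 67 changed 2-fold and 55 of 66 changed 4-fold, and 11 of its 132 calls were unchanged genes. Far fewer genes were changed there than were called between the real days, and each gene was drawn independently. These rates therefore need not hold for the real comparison. With 1 list lowered 1.5-fold in a simulation without correlated genes, camera called that list and 0 others. Alternatives covered the scaling factors, the count filter, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for loci with a mean of at least 1 TPM, the replicate block, the loss of each library, and the removal of organelle loci; fits without rRNA loci were added after seeing the data.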

Results

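Bulk RNA-seq libraries were analysed from callus of Arabidopsis thaliana, accession Col-0, the standard laboratory strain. Callus is a mass of dividing cells that forms when cut tissue is cultured with the hormones of a callus-inducing medium. Leaves of 2-week-old seedlings were the explants, and callus was collected on day 7 and day 12 of culture, with 3 biological replicates per day. The tables held total counts of 7412972, 10746277 and 8901518 for day 7 replicates 1, 2 and 3, and of 9944126, 10426265 and 4927953 for day 12 replicates 1, 2 and 3. The shallowest library, day 12 replicate 3, had 3.90% of its counts on rRNA loci and 3.51% on mitochondrial loci, against 0.121% and 0.112% in day 7 replicate 2. The comparison asked which genes differed between callus of 7 and 12 days. No leaf sample was analysed here, so every value is relative to day 7 callus.

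Between day 7 and day 12, 26 of 29 mitosis genes, 15 of 25 DNA replication genes, 19 of 31 genes of the photosynthetic light reactions and 5 of 10 shoot epidermis genes fell. Of the phosphate starvation genes 14 of 16 rose, as did 7 of 11 endodermis and suberin genes and 13 of 16 circadian clock genes. As whole lists none of these passed with an estimated correlation (lowest adjusted p = 0.118), and by fry the adjusted p was 0.0519 for the light reactions and 0.0673 for endodermis and suberin. PHO2 (AT2G33770), a ubiquitin-conjugating enzyme that limits phosphate uptake, rose from 192 ± 21.9 to 768 ± 169 CPM (SD, n = 3 per day). KN (AT1G08560), the syntaxin that builds the new wall at cell division, fell from 125 ± 4.22 to 67.3 ± 4.99 CPM. LTP2 (AT2G38530), an abundant lipid-transfer protein of the epidermis, fell from 2123 ± 317 to 914 ± 42.2 CPM. ASFT (AT5G41040), which adds ferulate to suberin, rose from 3.49 ± 1.58 to 21.3 ± 6.60 CPM. Of 18364 genes tested with edgeR's quasi-likelihood test, 4616 passed a Benjamini-Hochberg adjusted p of 0.05, 2324 of them higher on day 12 and 2292 lower. At least a 2-fold change was fitted for 1112 of these, 741 higher and 371 lower. The 3 libraries of one day lay wholly above those of the other for 8027 genes, 43.7% of those tested, where chance gives 10%. The number called was 2529 without day 7 replicate 1, with 1281 higher, 1248 lower and 709 changed at least 2-fold, and 2910 without day 7 replicate 2, with 1449 higher and 1461 lower. Without day 7 replicate 3, 1523 genes were lower. The limma test on log2(TPM + 1) called 1080 genes, 796 higher on day 12 and 284 lower.

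**Figure D1:**
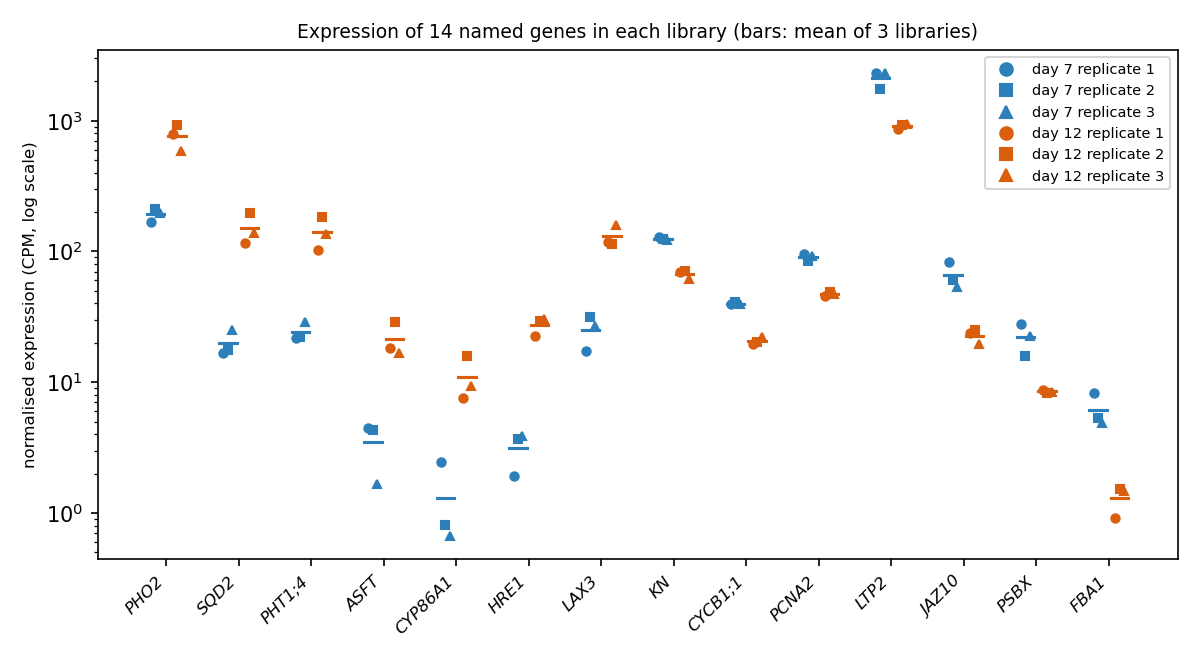
Expression in CPM on a log scale for 14 named genes. Each point is 1 library, colour marks the day, shape marks the replicate number and the bar is the mean of 3 libraries; for each gene drawn, the day 12 libraries lie entirely above or entirely below those of day 7.

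Most of the genes of largest fitted rise stood highest in day 12 replicate 2. PUB54 (AT1G01680), a U-box protein, stood at 18.9, 107 and 6.14 CPM in day 12 replicates 1, 2 and 3, with 4 counts over the day 7 libraries (log2 change 8.14 ± 1.95 (SE), adjusted p = 0.0433). Day 12 replicate 2 was also the highest library for the natriuretic peptide gene PNP-A (AT2G18660, 8.11 ± 1.98, adjusted p = 0.0455) and for cwINV6 (AT5G11920, 6.34 ± 1.37, adjusted p = 0.0307). The same held for NIMIN1 (AT1G02450, 6.43 ± 1.65, adjusted p = 0.0439), which encodes a partner of the immune regulator NPR1 (AT1G64280). TOM20-1 (AT3G27070), of the family of mitochondrial import receptors, had 1 count on day 7 and 341 on day 12, a ratio of 376 with a 95% counting interval from 66.9 to 14875. Without day 12 replicate 2 the log2 changes were 6.34 for PUB54, 6.27 for PNP-A, 5.89 for TOM20-1, 4.61 for NIMIN1 and 4.85 for cwINV6, with adjusted p of 0.00268, 0.00430, 0.00539, 0.00917 and 0.00105. None of these calls held without any single day 7 library, the adjusted p without day 7 replicate 1 being 0.142, 0.147, 0.184, 0.137 and 0.117 in that order. Without day 7 replicate 2 the values were 0.136, 0.141, 0.142, 0.1999 and 0.1195, and without day 7 replicate 3 they were 0.136, 0.135, 0.1297, 0.137 and 0.106. Without day 7 replicate 2, which held every day 7 count of NIMIN1, its fitted log2 change was 9.81; that of PNP-A was 7.41 there and 9.32 without day 7 replicate 3, and that of TOM20-1 was 9.72 without day 7 replicate 1. Without day 12 replicate 1 the adjusted p was 0.0578 for PUB54, 0.0598 for PNP-A and 0.0519 for NIMIN1. BGLU35 (AT1G51470), a beta-glucosidase gene, stood at 5.92, 4.39 and 10.2 CPM in day 12 replicates 1, 2 and 3; it had 1 count on day 7 and 152 on day 12, a ratio of 167 with a counting interval from 29.6 to 6654, that count being in day 7 replicate 2.

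Among the genes of largest fitted fall, LTP4 (AT5G59310), a lipid-transfer protein gene, fell by 4.79 ± 0.49 on the log2 scale (adjusted p = 0.00185). The subtilase gene ATSBT5.2 (AT1G20160) fell by 4.45 ± 0.75 (adjusted p = 0.00525). ESM1 (AT3G14210), known from glucosinolate breakdown, fell by 4.39 ± 0.82 (adjusted p = 0.0110) and SAG13 (AT2G29350), a senescence-associated gene, by 3.81 ± 0.89 (adjusted p = 0.0212). The aquaporin gene PIP2E (AT2G39010) fell by 3.00 ± 0.60 (adjusted p = 0.0130) and the methionine sulfoxide reductase gene MSRB7 (AT4G21830) by 2.89 ± 0.36 (adjusted p = 0.00199). Without day 12 replicate 2 the adjusted p was 0.0640 for ESM1, 0.0902 for SAG13 and 0.0728 for PIP2E, and without day 12 replicate 1 it was 0.0516 for ESM1 and 0.0727 for SAG13. Without day 7 replicate 1 the log2 changes of ATSBT5.2, ESM1, SAG13 and PIP2E were -3.69, -3.52, -2.68 and -2.24, and without day 12 replicate 2 that of ATSBT5.2 was -5.36.

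Gene lists fixed beforehand were tested with camera at a preset correlation, and 13 of 32 passed an adjusted p of 0.05, 6 upward and 7 downward. None of the 32 passed with a correlation estimated from the libraries, where 4 had an unadjusted p under 0.05. On log2(TPM + 1) fewer genes passed in each of several lists, with 3 mitosis, 3 DNA replication and 3 shoot epidermis genes lower and 5 clock genes higher. rRNA loci held from 1.67% (day 7 replicate 2) to 30.7% (day 7 replicate 1) of the TPM of a library. After TPM was rescaled without them, a fit chosen after seeing the data, 3769 genes were called over all genes tested, against 1080 before. Other groupings of the libraries, each of which still set 2 libraries of a day against 1, also gave many camera calls, up to 18 lists. The fry test called 10 lists between the days, and its adjusted p is given beside each of the lists that camera called. Counts of genes in a list are those passing the test over all genes, unless given as adjusted over the list alone.

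Mitosis and cytokinesis genes fell together: 26 of 29 tested genes fell and 0 rose, with 27 lower when adjusted over the list alone. The median log2 change was -0.74 (camera adjusted p = 3.02e-21, fry adjusted p = 0.00154; adjusted p = 0.118 with an estimated correlation). KN fell by 0.89 ± 0.09 on the log2 scale (adjusted p = 0.00141). The mitotic cyclin gene CYCB1;1 (AT4G37490) fell by 0.96 ± 0.10 (adjusted p = 0.00154) and the Aurora kinase gene AUR1 (AT4G32830) by 0.87 ± 0.10 (adjusted p = 0.00180). Among DNA replication and S phase genes 15 of 25 fell and 0 rose, 19 lower when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 1.28e-09, fry adjusted p = 0.0122; adjusted p = 0.364 with an estimated correlation). The sliding clamp gene PCNA2 (AT2G29570) went from 90.9 ± 6.25 to 47.4 ± 1.76 CPM, and TSO2 (AT3G27060), a ribonucleotide reductase subunit, from 190 ± 9.45 to 117 ± 8.78 CPM. The replicative helicase gene MCM4 (AT2G16440) fell by 0.78 ± 0.11 (adjusted p = 0.00271). Of 8 tested inhibitors of cyclin-dependent kinases, KRP1 (AT2G23430) rose by 1.90 ± 0.38 (adjusted p = 0.00882), KRP2 (AT3G50630) rose by 0.73 ± 0.17 (adjusted p = 0.0146) and KRP3 (AT5G48820) fell by 1.04 ± 0.26 (adjusted p = 0.0195). When adjusted over the list alone 3 of these genes were higher and 2 lower, and camera did not call the list (adjusted p = 0.689). With upper-quartile factors, with library sizes alone or by limma-voom 2 fell, and on log2(TPM + 1) 1 rose and 0 fell. KRP2 lost its call without day 7 replicate 1 (adjusted p = 0.0548) or 2 (0.0551). KRP3 lost its call without day 7 replicate 1 (0.0594) or 3 (0.0720) or day 12 replicate 1 (0.0634). In the ribosome biogenesis list APUM24 (AT3G16810) fell by 0.40 ± 0.11 and NOP56 (AT1G56110) by 0.36 ± 0.11, 2 of 13 genes and 0 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.505). Neither of these calls held without day 7 replicate 1 (adjusted p 0.0728 for APUM24 and 0.106 for NOP56), day 7 replicate 2 (0.0505 and 0.102), day 7 replicate 3 (0.0819 and 0.0643) or day 12 replicate 2 (0.0555 and 0.0707). NOP56 also lost its call without day 12 replicate 1 (0.0578).

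In the light reactions list 19 of 31 tested genes fell and 0 rose, 28 lower when adjusted over the list alone, with a median log2 change of -1.06 (camera adjusted p = 1.61e-11, fry adjusted p = 0.0519; adjusted p = 0.442 with an estimated correlation). The number that fell was 8 without day 7 replicate 1, 11 without day 7 replicate 3 and 10 without day 12 replicate 1 or 3. DRT112 (AT1G20340), which encodes plastocyanin, went from 16.7 ± 4.72 to 5.45 ± 0.70 CPM (adjusted p = 0.00311), and the photosystem II gene PSBX (AT2G06520) from 22.1 ± 5.90 to 8.52 ± 0.24 CPM (adjusted p = 0.00330). LHCB1.1 (AT1G29920), a light-harvesting protein gene with near-identical copies between which reads can be split, fell by 3.39 ± 0.54 (adjusted p = 0.00388). Of 12 carbon fixation and photorespiration genes 7 fell and 0 rose, 10 lower when adjusted over the list alone, with a median of -1.49 (camera adjusted p = 3.45e-05, fry adjusted p = 0.0384; adjusted p = 0.420 with an estimated correlation). The Calvin cycle genes FBA1 (AT2G21330) and SBPASE (AT3G55800) fell by 2.23 ± 0.36 and 2.08 ± 0.45. RBCS3B (AT5G38410), a Rubisco small subunit gene with close copies, had 64 counts on day 7 and 1 on day 12, in replicate 3, a ratio of 58.1 with a counting interval from 10.1 to 2331. Of 13 chlorophyll biosynthesis genes CRD1 (AT3G56940) fell by 1.18 ± 0.20 (adjusted p = 0.00494) and CHLI1 (AT4G18480) by 0.64 ± 0.15 (adjusted p = 0.0138), 5 being lower and 0 higher when adjusted over the list alone. The median log2 change of the list was -0.53, the camera adjusted p was 0.0338 and the fry adjusted p was 0.0673 (adjusted p = 0.551 with an estimated correlation). The camera p of the chlorophyll list was 0.0727 by limma-voom, 0.0583 without day 7 replicate 1, 0.0577 without day 7 replicate 3 and 0.0973 without day 12 replicate 3. CHLI1 had an adjusted p of 0.0501 without day 7 replicate 1. With the replicate number as a block 4 genes of this list fell. Among 6 greening regulators HY5 (AT5G11260) rose by 0.55 ± 0.12, GLK1 (AT2G20570) fell by 2.19 ± 0.62 and SIG6 (AT2G36990) fell by 0.77 ± 0.23, with 1 higher and 2 lower when adjusted over the list alone (camera adjusted p of the list = 0.694). The adjusted p of GLK1 and SIG6 was 0.0940 and 0.124 without day 7 replicate 1, 0.0590 and 0.118 without day 7 replicate 2, 0.0871 and 0.0565 without day 7 replicate 3, and 0.0695 and 0.110 without day 12 replicate 2. It was 0.0590 for SIG6 by DESeq2, 0.0699 for GLK1 without day 12 replicate 3, and 0.0927 for SIG6 without day 12 replicate 1, where GLK1 fell by 3.35. Without day 12 replicate 2 the log2 change of GLK1 was -1.61.

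Among shoot epidermis, cuticle and stomata genes 5 of 10 tested fell and 0 rose, 6 lower when adjusted over the list alone. The list had a median log2 change of -0.86, with a camera adjusted p of 6.35e-05 and a fry adjusted p of 0.0362 (adjusted p = 0.420 with an estimated correlation). LTP2 fell by 1.22 ± 0.12 (adjusted p = 0.00141), FDH (AT2G26250), a fatty acid elongase gene of the epidermis, by 1.13 ± 0.16 (adjusted p = 0.00300), and PDF2 (AT4G04890), a homeodomain regulator of epidermal identity, by 0.77 ± 0.16 (adjusted p = 0.00919). The number that fell was 3 without day 12 replicate 2. In day 7 replicate 2 the light reactions, carbon fixation and epidermis lists already stood lower than in day 7 replicate 1, with medians of -0.40 against 0.36, -0.41 against 0.45 and -0.31 against 0.21 relative to the day 7 mean.

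Among endodermis and suberin genes 7 of 11 tested rose and 0 fell, with 8 higher and 1 lower when adjusted over the list alone. That list had a median log2 change of 1.24, a camera adjusted p of 0.00289 and a fry adjusted p of 0.0673 (adjusted p = 0.488 with an estimated correlation). The number that rose was 4 without day 12 replicate 1, and 1 gene fell with the replicate number as a block or by DESeq2. ASFT rose by 2.62 ± 0.37 (adjusted p = 0.00370), and the fatty acid hydroxylase genes of suberin synthesis CYP86A1 (AT5G58860) and CYP86B1 (AT5G23190) rose by 3.13 ± 0.51 (adjusted p = 0.00494) and 3.90 ± 0.73 (adjusted p = 0.00772). The log2 changes of CYP86A1 and CYP86B1 were 3.87 and 4.77 without day 7 replicate 1, and without day 12 replicate 2 that of CYP86B1 was 3.29. The Casparian strip genes CASP1 (AT2G36100) and CASP2 (AT3G11550), chosen after their values were seen, had 0 counts in each day 7 library and 40 and 12 counts over the day 12 libraries. They were too low to test, and against a floor of 3 counts over the day 7 libraries CASP1 was at least 14.3-fold higher and CASP2 at least 4.28-fold higher. Markers of the other vascular and root cell types gave no camera call. Of 11 phloem genes PP2-A1 (AT4G19840) fell by 2.45 ± 0.38 (adjusted p = 0.00532) and CVP2 (AT1G05470) by 0.40 ± 0.13 (adjusted p = 0.0488), with 1 lower and 0 higher when adjusted over the list alone. The camera adjusted p of the phloem list was 0.0558, and it was 0.0195 with the replicate number as a block, 0.00458 without day 7 replicate 2, 0.0120 without day 12 replicate 2, 0.0260 with no count filter and 0.00410 on log2(TPM + 1). With an estimated correlation it was 0.551, and 0.505 with the block. CVP2 lost its call without any single library, with an adjusted p of 0.137, 0.140 and 0.0618 without day 7 replicates 1, 2 and 3 and of 0.0636, 0.0788 and 0.108 without day 12 replicates 1, 2 and 3. Its adjusted p was 0.0550 with RLE factors, 0.0960 by DESeq2, 0.0549 by limma-voom and 0.0506 without organelle loci, and its call was also lost with no count filter. No gene of the xylem (17 tested, camera adjusted p = 0.440), procambium (7 tested, 0.579) or root epidermis and root hair (5 tested, 0.620) lists passed; their lowest p-values were those of MYB63 (AT1G79180, log2 change 0.56 ± 0.19, adjusted p = 0.0636, and 0.0467 with the replicate block), MP (AT1G19850, -0.30 ± 0.11, adjusted p = 0.0839, and 0.0294 with the block; -0.19 without day 12 replicate 2) and LRX1 (AT1G12040, 0.847 ± 0.472 and 2.09 ± 0.851 CPM, adjusted p = 0.105). None passed when adjusted over the list alone. With the replicate block 5 xylem genes were higher and 2 lower, and by DESeq2 2 were higher. Chosen after their values were seen, these were MYB63, the secondary wall cellulose synthase genes CESA4, CESA7 and CESA8 and the laccase gene LAC4 (blocked adjusted p = 0.0128, 0.0118, 0.0187 and 0.0350 for the last 4), and, on the lower side, the xylem peptidase genes XCP1 and XCP2 (0.0235 and 0.0317).

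Phosphate starvation genes gave the highest list median, 2.98 on the log2 scale, with 14 of 16 tested genes higher on day 12 and 1 lower, and 15 and 1 when adjusted over the list alone (camera adjusted p = 1.46e-17, fry adjusted p = 0.0155; adjusted p = 0.285 with an estimated correlation). SQD2 (AT5G01220), which makes a sulfolipid that replaces phospholipids, rose by 2.92 ± 0.24 (adjusted p = 0.00143), and the phosphate transporter gene PHT1;4 (AT2G38940) by 2.53 ± 0.24 (adjusted p = 0.00180). PHO2 rose by 2.00 ± 0.17 (adjusted p = 0.00141), although its transcript is known to be cut by a microRNA under phosphate shortage, and the ribonuclease gene RNS1 (AT2G02990), known to be induced by that shortage, fell by 0.79 ± 0.19 (adjusted p = 0.0199). RNS1 lost its call without day 7 replicate 1 (adjusted p = 0.0693) or 3 (0.0522) or day 12 replicate 1 (0.0740) or 3 (0.0577). The number of genes that rose was 9 without day 7 replicate 2. Of 7 iron deficiency genes 4 rose and 0 fell, the same counts holding when adjusted over the list alone. The median log2 change of the list was 1.07, the camera adjusted p was 0.00164 and the fry adjusted p was 0.0113 (adjusted p = 0.285 with an estimated correlation). The regulator gene BHLH100 (AT2G41240) rose by 2.12 ± 0.35 (adjusted p = 0.00433) and the ferric reductase gene FRO2 (AT1G01580) by 1.87 ± 0.41 (adjusted p = 0.0135). FER1 (AT5G01600), which encodes the iron store ferritin and is known to be induced by iron excess, rose by 1.07 ± 0.17 (adjusted p = 0.00528). Of 8 nitrogen uptake and assimilation genes NIA1 (AT1G77760), AMT1;3 (AT3G24300) and NRT2.5 (AT1G12940) rose by 0.98 ± 0.22, 1.17 ± 0.34 and 1.88 ± 0.58, with 4 higher and 0 lower when adjusted over the list alone. The adjusted p of AMT1;3 was 0.0377, and 0.0547 with the replicate block. The list had a camera adjusted p of 0.0838, which was 0.0348 with the replicate block and 0.0187 without day 7 replicate 2, and a fry adjusted p of 0.0362. With an estimated correlation the adjusted p was 0.420, and 0.505 with the block. None of these 3 genes passed without day 7 replicate 1 (adjusted p 0.0752, 0.112 and 0.130) or day 12 replicate 1 (0.0629, 0.0886 and 0.0912). NIA1 also lost its call without day 12 replicate 2 (0.0617), AMT1;3 without day 7 replicate 3 (0.118) or day 12 replicate 3 (0.0928), and NRT2.5 without day 7 replicate 2 (0.147) or day 12 replicate 2 (0.0933) or 3 (0.0913). The log2 change of NRT2.5 was 2.59 without day 7 replicate 3.

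**Figure D2:**
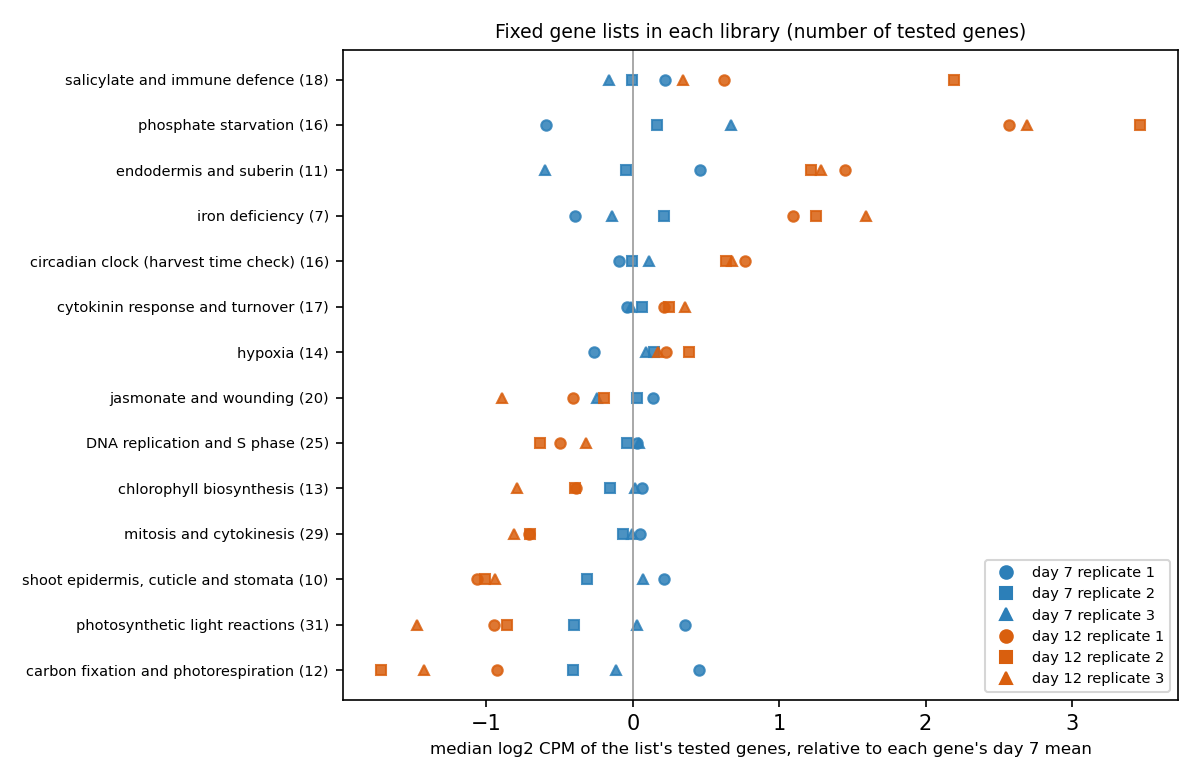
Median log2 CPM of each list's tested genes in each library, relative to each gene's day 7 mean, for the 13 lists called by camera and the salicylate list; the number of tested genes is in brackets, colour marks the day and shape the replicate. Phosphate starvation stood at 2.57, 3.46 and 2.69 in the day 12 libraries, and salicylate and immune defence at 0.62, 2.19 and 0.34.

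Regulators of callus and root primordia went both ways. Of 19 tested, 2 rose and 4 fell (4 and 4 with the replicate block), 3 and 5 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.579). ARF7 (AT5G20730), an auxin response factor gene, rose by 0.50 ± 0.11 (adjusted p = 0.0115). PLT3 (AT5G10510), a root stem cell regulator gene, fell from 427 ± 35.7 to 305 ± 38.4 CPM (adjusted p = 0.0150), and the receptor kinase gene ACR4 (AT3G59420) fell by 0.64 ± 0.16 (adjusted p = 0.0196). WOX11 (AT3G03660) rose by 1.71 ± 0.45 (adjusted p = 0.0465), standing at 120, 205 and 68.8 CPM on day 12, and LBD16 (AT2G42430) fell by 0.80 ± 0.22 (adjusted p = 0.0297). The calls of WOX11 and LBD16 were both lost without day 7 replicate 1 (adjusted p 0.144 and 0.0934), day 7 replicate 3 (0.137 and 0.0507), day 12 replicate 1 (0.0941 and 0.0588) or day 12 replicate 2 (0.0613 and 0.0536). WOX11 also lost its call without day 7 replicate 2 (0.0830), with library sizes alone (0.0523) and with no count filter (0.0956), and LBD16 without day 12 replicate 3 (0.0590). PLT3 had an adjusted p of 0.0553 without day 7 replicate 1, and ACR4 of 0.0541 and 0.0667 without day 7 replicates 2 and 3. The log2 changes of WOX5 (AT3G11260), PLT1 (AT3G20840) and PLT2 (AT1G51190) were -0.25 ± 0.20 (adjusted p = 0.397), 0.38 ± 0.16 (adjusted p = 0.129, 0.0406 with the replicate block, and 0.0312 without day 12 replicate 2) and -0.25 ± 0.13 (adjusted p = 0.184). That of WOX5 was -0.031 without day 7 replicate 1, -0.42 without day 7 replicate 2 and -0.13 without day 12 replicate 1. The value was 0.22 for PLT1 without day 12 replicate 3, and -0.13 and -0.15 for PLT2 without day 7 replicate 3 and day 12 replicate 2. LBD29 (AT3G58190) was too low to test, with 51 counts on day 7 and 4 on day 12, a ratio of 11.9 with a counting interval from 4.38 to 45.4.

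Of 10 tested shoot meristem and regeneration genes, KNAT1 (AT4G08150) rose by 1.69 ± 0.33 (adjusted p = 0.00765) and CUC1 (AT3G15170) by 1.67 ± 0.51 (adjusted p = 0.0426, and 0.0542 with the replicate block), with 4 higher and 1 lower when adjusted over the list alone. CUC1 had an adjusted p of 0.137 and 0.135 without day 7 replicates 1 and 3, and of 0.114, 0.0912 and 0.0837 without day 12 replicates 1, 2 and 3; its log2 change was 2.35 without day 7 replicate 2. The list was not called by camera (adjusted p = 0.249, and 0.488 with an estimated correlation) but was by fry (adjusted p = 0.0205). With no count filter, by DESeq2 or on log2(TPM + 1) 1 gene of this list rose, and 1 fell by limma-voom, with upper-quartile factors, with library sizes alone or without organelle loci. STM (AT1G62360) had a log2 change of 0.99 ± 0.35 (adjusted p = 0.0662, 0.0387 with the replicate block, and 0.0204 without day 7 replicate 2). WUS (AT2G17950), the stem cell organiser, had 0 counts in all 6 libraries, which allows up to 0.111 CPM over the day 7 libraries and 0.119 CPM over those of day 12. ESR1 (AT1G12980) had 13 counts on day 7 and 2 on day 12, a ratio of 6.08 with a counting interval from 1.38 to 55.5. Of the embryo and seed maturation list only AGL15 (AT5G13790) and BBM were tested and neither passed; AGL15 had a log2 change of -0.38 ± 0.17 (adjusted p = 0.125, and 0.0461 without day 12 replicate 2; log2 change -0.22 without day 12 replicate 3), and none passed when adjusted over the list alone.

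Of 17 tested cytokinin genes 5 rose and 0 fell, with the same counts when adjusted over the list alone. The list had a median log2 change of 0.26, with a camera adjusted p of 0.0338 and a fry adjusted p of 0.0263 (adjusted p = 0.424 with an estimated correlation). The receptor gene AHK3 (AT1G27320) went from 41.3 ± 3.63 to 79.2 ± 11.3 CPM (adjusted p = 0.00238), the cytokinin oxidase gene CKX5 (AT1G75450) rose by 0.71 ± 0.13 and the response regulator gene ARR6 (AT5G62920) by 0.66 ± 0.13. The camera p of this list was 0.0759 and 0.0920 without day 7 replicates 1 and 3 and 0.233 without day 12 replicate 3. With no count filter it was 0.306, with 5 higher and 1 lower of 25 genes, and on log2(TPM + 1) it was 0.0980, with 1 higher. The number that rose was 3 without day 7 replicate 1 or day 12 replicate 1 or 3, with upper-quartile factors and with library sizes alone. Auxin response and transport genes were split, with 3 of 22 higher and 4 lower, the same counts holding when adjusted over the list alone (camera adjusted p = 0.689). Without day 7 replicate 1 or day 12 replicate 3, 1 of these genes rose, and without day 7 replicate 2 or day 12 replicate 1, 2 fell. By DESeq2 5 rose, and on log2(TPM + 1) 1 rose and 1 fell. LAX3 (AT1G77690), an auxin influx carrier gene, rose from 25.1 ± 7.09 to 131 ± 26.0 CPM (adjusted p = 0.00187), while IAA5 (AT1G15580) and IAA30 (AT3G62100), genes of auxin response repressors, fell by 1.62 ± 0.24 and 0.54 ± 0.09. None of 7 auxin biosynthesis genes passed, also when adjusted over the list alone (camera adjusted p = 0.606); the lowest p was that of YUC9 (AT1G04180), with a log2 change of -0.45 ± 0.28 (adjusted p = 0.288), or -0.12 without day 7 replicate 2 and -0.25 without day 12 replicate 2.

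Of 20 jasmonate and wounding genes 4 fell and 1 rose, 7 and 1 when adjusted over the list alone, and 8 fell and 2 rose with the replicate block. That list had a median log2 change of -0.48, a camera adjusted p of 0.00767 and a fry adjusted p of 0.0770 (adjusted p = 0.488 with an estimated correlation). The repressor gene JAZ10 (AT5G13220) fell by 1.51 ± 0.17 (adjusted p = 0.00185), JAZ5 (AT1G17380) fell by 1.68 ± 0.29 and the lipoxygenase gene LOX3 (AT1G17420) by 1.76 ± 0.36, whereas the storage protein gene VSP1 (AT5G24780), known to be induced by jasmonate, rose by 2.29 ± 0.45 (adjusted p = 0.0121). The camera p of this list was 0.0600 without day 12 replicate 3. VSP1 had an adjusted p of 0.0608 without day 7 replicate 1 and a log2 change of 2.96 without day 7 replicate 2.

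In the salicylate and immune defence list 5 of 18 rose and 0 fell, 6 and 0 when adjusted over the list alone (camera adjusted p = 0.0663, and 2.49e-04 with the replicate block; with an estimated correlation 0.768, and 0.505 with the block). The camera p was 0.0360 without day 7 replicate 1, and 0.0249, 1.79e-04 and 0.00125 without day 12 replicates 1, 2 and 3. It was 0.0401 with upper-quartile factors, 0.0374 with library sizes alone, 0.0140 by DESeq2, where 8 genes rose, and 0.0260 with no count filter, where 1 of 22 genes rose. On log2(TPM + 1) it was 3.10e-04, on log2(TPM + 0.1) 0.00212, and on TPM rescaled without rRNA loci, a fit chosen after seeing the data, 0.0247. PAD4 (AT3G52430) rose by 2.69 ± 0.57 (adjusted p = 0.0265, and 0.0643 with the replicate block), NPR1 by 0.69 ± 0.19 (adjusted p = 0.0321) and CBP60G (AT5G26920) by 2.01 ± 0.52 (adjusted p = 0.0343), each highest in day 12 replicate 2. No gene of this list passed as higher when any single day 7 library was left out. The adjusted p of PAD4, NPR1 and CBP60G was 0.0852, 0.114 and 0.0806 without day 7 replicate 1. It was 0.102, 0.0771 and 0.120 without day 7 replicate 2, and 0.0915, 0.0956 and 0.122 without day 7 replicate 3. The fitted rises changed little in these fits. Without day 7 replicates 1, 2 and 3 the log2 change was 2.80, 2.58 and 2.68 for PAD4. It was 0.67, 0.73 and 0.68 for NPR1, and 2.26, 1.89 and 1.88 for CBP60G. The number that rose was 3 without day 12 replicate 1, 8 without day 12 replicate 2 and 9 without day 12 replicate 3. The log2 changes of PAD4, NPR1 and CBP60G were 1.89, 0.41 and 1.24 without day 12 replicate 2. Of 14 hypoxia genes 3 rose and 1 fell, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0368, fry adjusted p = 0.160; adjusted p = 0.736 with an estimated correlation). HRE1 (AT1G72360), an ethylene response factor gene, rose from 3.15 ± 1.09 to 27.4 ± 4.30 CPM (adjusted p = 0.00141), HRA1 (AT3G10040) rose by 0.73 ± 0.19 (adjusted p = 0.0297, and 0.0654 with the replicate block) and the sucrose synthase gene SUS1 (AT5G20830), known to be induced by low oxygen, fell by 0.44 ± 0.11 (adjusted p = 0.0193). The camera p of the hypoxia list was 0.157 without day 7 replicate 1 and 0.125 without day 12 replicate 2, and it was 0.107 by limma-voom, 0.0980 on log2(TPM + 1) and 0.102 on TPM rescaled without rRNA loci. The number that rose was 1 without day 7 replicate 1 or 3 and on log2(TPM + 1). HRA1 and SUS1 had an adjusted p of 0.0983 and 0.0592 without day 7 replicate 1, 0.0596 and 0.0506 without day 7 replicate 2, and 0.0805 and 0.0668 without day 7 replicate 3. Without day 12 replicate 1 the adjusted p of SUS1 was 0.0546 and the log2 change of HRA1 was 0.48.

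Clock genes rose together, 13 of 16 tested and 0 falling, 14 higher when adjusted over the list alone. The median log2 change of the list was 0.70, the camera adjusted p was 4.52e-09 and the fry adjusted p was 0.00424 (adjusted p = 0.118 with an estimated correlation). PRR7 (AT5G02810) went from 48.9 ± 3.77 to 105 ± 13.2 CPM (adjusted p = 0.00143), FKF1 (AT1G68050) from 8.38 ± 1.85 to 23.3 ± 1.86 CPM (adjusted p = 0.00187) and GI (AT1G22770) from 78.0 ± 4.57 to 127 ± 12.8 CPM (adjusted p = 0.00287). The hour of harvest was not given in the sources used here.

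The remaining lists were not called by camera. Among 26 chromatin and DNA methylation regulators 7 rose and 2 fell, 7 and 3 when adjusted over the list alone (camera adjusted p of the list = 0.529), with the histone demethylase gene JMJ30 (AT3G20810) rising by 1.21 ± 0.11, unlike the DNA methylation genes CMT3 (AT1G69770) and DDM1 (AT5G66750), which fell by 0.84 ± 0.11 and 0.59 ± 0.10. Without day 7 replicate 1 or 2 the number that rose was 3, without day 12 replicate 3 the number that fell was 4, and on log2(TPM + 1) 1 rose and 0 fell. Of 17 wall-loosening genes 3 fell, among them EXPA10 (AT1G26770) and EXPA6 (AT2G28950) by 1.51 ± 0.24 and 0.72 ± 0.15, and XTH24 (AT4G30270) rose by 2.19 ± 0.40, with 3 lower and 2 higher when adjusted over the list alone (camera adjusted p of the list = 0.249). With the replicate block 5 fell and 2 rose. XTH24 had an adjusted p of 0.0514, 0.0638 and 0.0566 without day 7 replicates 1, 2 and 3. Of 16 senescence genes SAG21 (AT4G02380) and NAP (AT1G69490) rose by 0.72 ± 0.15 and 0.62 ± 0.13, and SAG13 was among the 2 that fell, the same counts holding when adjusted over the list alone (camera adjusted p of the list = 0.453). By DESeq2 or with the replicate block 4 of the senescence genes rose, by limma-voom 1 fell, and on log2(TPM + 1) 0 rose and 1 fell. SAG13 lost its call without day 12 replicate 1 (adjusted p = 0.0727) or 2 (0.0902). Of 18 glutathione transferase and ROS genes APX1 (AT1G07890) and CSD2 (AT2G28190) fell by 0.47 ± 0.09 and 0.63 ± 0.12 and UPB1 (AT2G47270), a regulator of peroxidase genes, rose by 1.28 ± 0.26, with 3 lower and 2 higher in all and when adjusted over the list alone (camera adjusted p of the list = 0.995). The number that rose was 1 with upper-quartile factors, with library sizes alone and with no count filter, and without day 7 replicate 1, 2 or 3 or day 12 replicate 1 or 2. On log2(TPM + 1) 0 fell. Of 9 flavonoid genes PAL1 (AT2G37040) alone passed, rising by 0.68 ± 0.16, as it did when adjusted over the list alone (camera adjusted p of the list = 0.505), and its adjusted p was 0.0608 and 0.0690 without day 7 replicates 2 and 3. In the heat shock list, whose median was 0.08 and mean -0.05, HSP101 (AT1G74310) rose by 0.45 ± 0.11 and HSP17.6II (AT5G12020) fell from 4.67 ± 3.49 to 1.04 ± 0.19 CPM, the only calls among 10 genes, with 2 higher and 2 lower when adjusted over the list alone (camera adjusted p of the list = 0.807). The number that fell was 2 with upper-quartile factors, library sizes alone, no count filter, the replicate block or DESeq2, where 2 rose, and 0 by limma-voom, where 2 rose, or on log2(TPM + 1). Both calls were lost without day 7 replicate 1 (adjusted p 0.0504 and 0.0988), day 7 replicate 3 (0.0524 and 0.149) or day 12 replicate 2 (0.0605 and 0.125). HSP101 also lost its call without day 7 replicate 2 (0.0854), and HSP17.6II without day 12 replicate 1 (0.112) or 3 (0.107). The log2 change of HSP17.6II was -2.10, and -1.38 without day 7 replicate 3.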

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

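These loci were chosen for mention, and their counts compared, only after the tables had been seen. The rRNA locus AT3G41979 had 0 counts in all 6 libraries of the count table but reached 113858 TPM, the lowest library standing at 5948 TPM. AT2G01020, another rRNA locus, had the same TPM in each library and 1145, 60, 618, 833, 219 and 558 counts in day 7 replicates 1 to 3 and day 12 replicates 1 to 3. AT3G41979 is listed as a signal in a table that the main comparison did not use. In all, 219 loci had a summed TPM of at least 1 and 0 counts in each library, and 218 of them were not rRNA. The count and TPM tables thus assign reads differently, and no explanation was tested. Groups of 3 libraries are too small for the outlier test, so no library was examined that way.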

How the results depend on the processing

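Alternatives that leave out rRNA loci were added after seeing the data. The numbers of genes called, higher and lower stayed within 1.5 times of 4616, 2324 and 2292 under every count setting with all libraries. On log2(TPM + 1) they were 1080, 796 and 284, and on log2(TPM + 0.1) 1083, 802 and 281, so 73.7% and 74.1% of the calls were higher against 50.3%. After TPM was rescaled without rRNA loci, 3769 genes were called, 53.9% of them higher and 3526 shared with the 4616, which points to the rRNA share of TPM as part of the cause. Leaving out 1 library gave 2529 to 4342 called, 1281 to 2286 higher, 1248 to 2056 lower, 709 to 1184 changed at least 2-fold and 11 to 15 lists; fewer libraries enter those fits. A test against a 1.5-fold change called 326 genes in place of the 1112 changed at least 2-fold, a stricter null by construction. Camera called 13 lists, 0 with an estimated correlation; fry called 10. The replicate block called 5167 genes, 4394 of them shared, and 16 lists; apart from phloem, nitrogen, salicylate, PAD4, CUC1, AMT1;3 (0.0547), HRA1, MYB63 (0.0467), MP (0.0294), PLT1, STM and 6 more xylem genes (CESA4, CESA7, CESA8, LAC4, XCP1 and XCP2) it changed no other call among the lists and the named genes of the report. Of 1913 comparisons of named genes with an alternative, 1662 kept direction and side of the threshold, 242 lost the call, 9 gained it and 0 reversed. The depth of day 12 replicate 3 limits genes under 0.609 CPM there.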

Other observations

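The tests of product-name families, of the salicylate and clock genes, and of gene copies and low counts among leaf genes were chosen only after the results were seen. Gene families share a product name in the reference. Of 225 families with at least 8 tested genes, camera at the preset correlation called 15, 4 upward and 11 downward; with an estimated correlation 0 were called and 4 had an unadjusted p under 0.05. Among genes named as histone superfamily proteins 19 of 28 fell and 0 rose (median -0.44, adjusted p = 1.26e-05, and 0.889 with an estimated correlation). AT2G37470 went from 58.7 ± 2.44 to 30.5 ± 1.80 CPM (SD, n = 3 per day). Where genes of this family are near-identical copies their reads cannot be told apart, so the 19 need not be separate falls. Several ribosomal protein families were lower, including 7 of 8 zinc-binding ribosomal proteins (median -0.62, adjusted p = 5.34e-05; adjusted p = 0.889 with an estimated correlation), although the ribosome biogenesis list was not called. Disease resistance genes of the TIR-NBS-LRR class, which encode intracellular immune receptors, were higher in 13 of 44 cases and lower in 0 (median 0.71, adjusted p = 8.01e-05, and 0.00155 without day 12 replicate 2; adjusted p = 0.889 with an estimated correlation). RPS4 of that class went from 9.81 ± 1.19 to 17.2 ± 1.36 CPM. In a family of 8 myb-like transcription factor genes 5 rose (adjusted p = 0.00845; adjusted p = 0.889 with an estimated correlation), among them HRS1, known from nitrate and phosphate signalling, by 1.57 ± 0.47.

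The 6 libraries can be split into groups of 3 and 3 in 10 ways, too few for a share under 0.05. For the genes changed, higher, lower and changed at least 2-fold, 1 of the 10 splits, the real one, gave a value as large; the real values were 4616, 2324, 2292 and 1112, and the highest other value was 0 by edgeR, with at most 720 genes at an unadjusted p under 0.05 against 7148. The number of lists called behaved otherwise: 5 of the 10 splits, the real one included, gave at least 13 lists, the highest other split giving 18. Of the 4 splits that part all 3 replicate pairs, the one that joins day 12 replicate 2 to day 7 replicates 1 and 3 gave the 18 lists and 0 genes. Each split other than the real one still sets 2 libraries of a day against 1 and so holds part of the day difference; the mitosis list was called in all 9 of them. Their list calls therefore do not tell differences between libraries of the same day from that part. For the product families 2 of the 10 splits gave at least 15, the highest other giving 16. By fry the real split called 10 lists and the highest other 0, with 15 and at most 2 at an unadjusted p under 0.05. Of the 13 lists called by camera, 4 had their lowest camera p in the real split (mitosis, phosphate starvation, DNA replication and clock) and 12 had their largest absolute median there, hypoxia being the exception. The other splits also put the day difference inside each group, which widens the spread there and shrinks the contrast. Fewer genes, fewer fry calls and smaller medians in those splits were therefore built in, and they do not count in favour of the real split.

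Salicylate and immune genes were highest in day 12 replicate 2. For 8 of 18 genes day 12 replicates 1 and 3 both exceeded all day 7 libraries, where chance gives 10% for a single gene. These genes were measured in the same libraries and are not independent replicates, so that share is descriptive only. A rise in day 12 replicate 2 alone is argued against by the edgeR fit without that library, in which 8 of the 18 rose. Its depth does not account for a median of 1.45 log2 units above day 12 replicate 1, since the depths differed by 0.07. A batch that raised these genes alike in both replicates numbered 2 is argued against by day 7 replicate 2. Its median gap to the other day 7 libraries was -0.0093, against 1.55 for day 12 replicate 2. Both libraries did have the lowest share of counts on rRNA loci for their day, 0.121% on day 7 and 0.422% on day 12. Their mitochondrial shares were also the lowest, 0.112% and 0.227%. A shared batch acting differently by day was not tested. What set day 12 replicate 2 apart stays open, and no biological explanation was tested.

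The clock list rose by medians of 0.55 for morning genes and 0.74 for the other genes of the list. The choice among the scaling alternatives made little difference, the lowest list median being 0.65. These alternatives gave medians over all tested genes between -0.046 and 0.079, so they could not have removed the rise. A larger error of scaling was not tested. A different hour of harvest was expected to give the morning genes and the other genes medians of opposite sign. That was not seen, and all 16 tested genes had positive log2 changes. The opposite expectation, a rise of all genes by about the same amount, was not met either, as the changes had an SD of 0.42. Because the harvest times are not known, a different hour of harvest may still account for the rise and cannot be told apart from a change with culture age.

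Among 53 leaf genes, 19 of 31 light reactions, 7 of 12 carbon fixation and 5 of 10 shoot epidermis genes fell, and 3 of the 53 had positive log2 changes. Reads shared within the LHCA, LHCB, RBCS, PSBO, PSBQ and FBA families are argued against as the only cause by 33 genes outside them, with a median of -1.09. Close copies in other families were not set apart, so shared reads there were not tested. Low counts are argued against by a median of -0.89 only for the 13 genes with a mean of at least 20 CPM on both days. The light reactions and carbon fixation genes named above stood under that level on day 12 (DRT112 at 5.45 and PSBX at 8.52 CPM) and are not covered. A candidate explanation is that fewer cells of the leaf explant remained on day 12. Across these genes, which are not independent replicates, the difference between day 7 replicates 1 and 2 correlated with that between day 7 replicate 3 and the day 12 mean (r = 0.51, permutation p = 6.00e-05, rho = 0.55), against r = 0.12 over all genes tested. A joint fall of these genes within the callus cells could give the same correlation, so the correlation does not favour either explanation. The value over all genes was not matched for expression level. Among the day 7 libraries, replicates 1 and 2 also stood furthest apart in the share of counts on rRNA loci, at 2.90% and 0.121%. A fall within the callus cells stays open and was not tested.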
